A study of Homo sapiens with 12 samples.

How the data were processed

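SLAM-seq was measured in 12 libraries of the human colon carcinoma line HCT116 and of a clone derived from it that carries a knock-in at TOP1 (KI). SLAM-seq adds 4-thiouridine to living cells, so that RNA made during labelling carries T-to-C conversions in its sequencing reads. Per the labels' protocols, cells were held in S phase with 2.5 mM thymidine, released into 400 ng/ml nocodazole and collected by mitotic shake-off. They were then labelled with 100 µM 4-thiouridine for 45 min, either at once (mid mitosis) or after 40 min in fresh medium (late mitosis). Asynchronous cells were the third state, and the labels give no thymidine or nocodazole for them. Mitotic and asynchronous libraries were also deposited apart. In comparisons between them, state is therefore not separable from drug treatment or from any batch. Each of the 6 groups had 2 libraries, prepared with a 3' tag kit that reads 1 end of polyadenylated transcripts. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

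The authors deposited 4 tables, for converted reads and for all reads, in mitotic and in asynchronous cells. The sample values in these deposited tables are on a log2 scale. The whole reads behind them were recovered: the deposited value is the log2 of the read count divided by 1 factor per library, plus a pseudocount of 1. All values came out whole within a tolerance of 0.01 reads (100% of values; largest deviation 0.0002255). The factors equalled median-of-ratios factors computed here over all 12 libraries together, to a ratio of 0.9998 to 1.0005, separately for converted and for all reads. The deposited tables also hold the authors' adjusted p-values and log2 fold changes for their own comparisons. Per the submitters' processing notes, the authors used DESeq2 1.26.0 and the GRCh38 build; the aligner and the conversion caller are not given in the sources used here. The authors' fold changes were turned where needed so that late stands over mid and KI over WT.

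Recovered depth was 5216055 to 8432894 reads per library over named genes, of which 517407 to 1089527 were converted. Each table held 1 unnamed entry, at most 0.0006476% of all reads, and 2 symbols altered to dates; all of these were left out. Converted reads are called new RNA here, and all reads, which include them, total RNA. Agreement in direction between new and total RNA is therefore not independent support. No unlabelled library was used here, so sequencing error, variants of the cell lines and conversions from labelling are not separated. The reads carry no molecular identifiers in the sources used here, so intervals cover counting error only.

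The design, the rule for named genes, 20 gene lists and most alternatives were fixed before the data were examined. A count model had been planned as the main test, and it was not run on the recovered whole reads. Because the deposited values are log2 values, the planned fallback was used instead: limma-trend on log2(value + 1), with limma 3.58.1 in R 4.3.3. Fold changes are on that scale, which understates changes of genes with few reads. Genes with at least 10 recovered reads in at least 2 libraries were tested. This left 7927 genes for new RNA and 11563 for total RNA in mitotic cells, and 8751 and 11409 in asynchronous cells. The 8 mitotic libraries were fitted together, and the 4 asynchronous libraries on their own. Calls are genes with a Benjamini-Hochberg adjusted p below 0.05. Comparisons of mitotic with asynchronous cells were added after the files showed that all 12 libraries had been scaled together; they were fitted on all 12 libraries, over 9205 genes for new and 11964 for total RNA. The late against mid comparisons and the KI against WT comparisons in mitosis share libraries with each other.

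The named genes are, for each new RNA comparison, the 8 higher and 8 lower genes with the greatest fold change among called genes that have at least 20 converted reads per library in the higher group, no overlap between the groups and an assigned symbol, together with up to 3 members of each list with the smallest adjusted p, and TOP1. For the genotype by time comparison the no-overlap condition cannot be applied to 4 groups, so it was left out and the highest group mean was used. Of the list members the text names, FOSB, KLF6, DUSP1 and ATF3 at mid, EGR2, CCN2, EGR1, CDKN1A and MDM2 in asynchronous cells and SGK1 in KI fall outside this rule and were chosen after their values were seen, as were genes named only because 2 comparisons shared them and ribosomal protein genes named only for their converted shares. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists. The estimated setting also uses the few residual degrees of freedom of the fit, so a loss under it does not measure correlation alone. Of 209 such tests in the design 48 passed and 0 with an estimated correlation; of 140 added against asynchronous cells 51 passed and 26 with it. Lists with fewer than 5 tested members were not tested. A gene that met the rule is not reported here. A group with no reads in any library was set to a floor of 3 reads per library to give a lower bound on the fold. Gene positions and lengths come from a reference table of the same build, GRCh38, in which 14503 of 14965 symbols were found. Shares of single libraries carry 95% Wilson intervals, and tests of library shares are two-sided exact permutation tests.

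The procedure was tested on simulated data with known fold changes, drawn from the real means with a spread that depended on the mean alone. Simulated genes therefore had no spread of their own, and no library was set apart from its group. Recovery and false calls in the real data can be worse than the values given here. For KI against WT at late, 62% of 4-fold and 17.7% of 2-fold changes were recovered in new RNA among 7574 genes, and 85.9% and 50% in total RNA among 11362 genes. For the genotype by time term in new RNA, 33.3% of 4-fold and 4.17% of 2-fold changes were recovered among 7557 genes. For KI against WT in asynchronous cells, 85.1% of 4-fold and 29.9% of 2-fold changes were recovered in new RNA among 8442 genes. For mid against asynchronous WT cells, 56.6% of 4-fold and 13.5% of 2-fold changes were recovered in new RNA among 8737 genes. False calls among unchanged genes numbered 1 to 6 per simulation.

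Alternatives covered the low-count filter, the samples in the fit, the replicate number as a block, scaling by all reads and leaving out each library. After the data were seen, trimmed mean of M-values scaling, pseudocounts of 0.5 and 5 and limma-voom on the recovered reads were added.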

Results

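New and total RNA were measured in HCT116 colon carcinoma cells (WT) and in a clone derived from them with a TOP1 knock-in (KI), in asynchronous growth, in mid mitosis and in late mitosis, with 2 libraries in each of the 6 groups. TOP1 encodes topoisomerase 1, which relaxes the supercoils that transcription puts into DNA. The series asks how its activity bears on transcription in mitosis and on the passage to G1. KI is a single clone, so genotype and clone were not separable. Recovered depth was 5216055 to 8432894 reads per library. The correlation between replicates across genes was 0.844 to 0.903 for new RNA and 0.949 to 0.971 for total RNA in mitotic cells.

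Converted reads made up 13.2% ± 0.248 (SD, n = 2) of all reads in asynchronous WT cells and 13.9% ± 0.106 (SD, n = 2) in asynchronous KI cells. In mitosis the shares were 9.92% ± 0.520 at mid and 10.3% ± 1.65 at late in WT, and 8.62% ± 0.355 and 9.27% ± 0.3995 in KI (SD, n = 2 each). The 8 mitotic libraries averaged 9.54% against 13.5% in the 4 asynchronous libraries, a difference of -4.00 percentage points (exact permutation test, p = 0.00202). That p is the smallest this test can give, and the test ignores genotype and time. State was not separable from drug treatment or batch in it. The 4 KI mitotic libraries lay -1.19 points from the 4 WT mitotic libraries (exact permutation test, p = 0.0571). With 2 libraries against 2 the smallest exact p is 0.333.

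**Figure D1:**
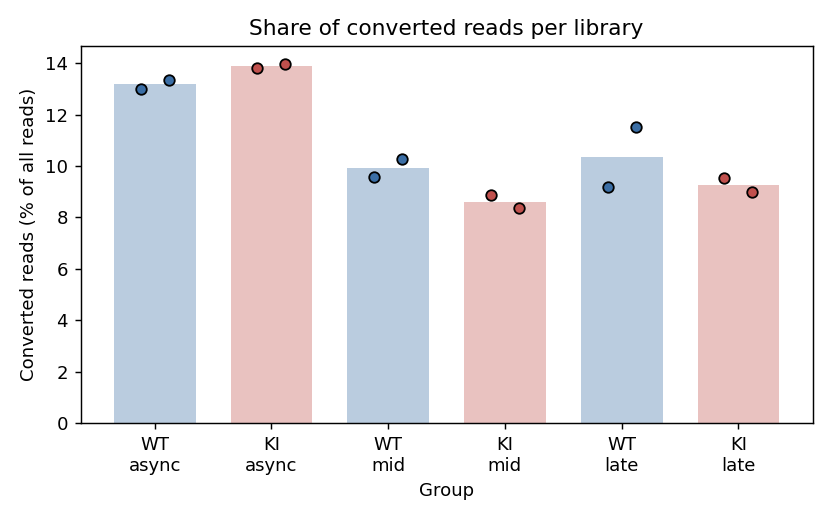
Share of converted reads (% of all reads, vertical axis) in each library by group; points are libraries and bars are group means. The mitotic libraries lie between 8.37% and 11.5%, all below the asynchronous libraries, which lie between 13% and 14%.

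TOP1 itself (chromosome 20, 41028822 to 41124487, GRCh38) had fewer reads in KI than in WT cells in each state. Total TOP1 RNA was 1.86-fold lower in KI at mid, with 1450 ± 14.3 normalised reads against 2692 ± 4.57 (SD, n = 2 each; limma-trend, adjusted p = 0.0189). At late it was 2.96-fold lower, 1042 ± 223 against 3048 ± 170.5 (SD, n = 2 each; limma-trend, adjusted p = 0.000119). New TOP1 RNA was 3.09-fold lower in KI at late (log2 -1.63, SE 0.27; limma-trend, adjusted p = 0.00263). At mid its log2 fold change was -0.70 (SE 0.27, limma-trend adjusted p = 0.419) in new RNA. In asynchronous cells the values were -0.81 for new RNA (limma-trend, adjusted p = 0.418) and -1.26 for total RNA (limma-trend, adjusted p = 0.0798), and neither passed the test. The change of the KI effect between mid and late was -0.92 in new RNA (limma-trend, adjusted p = 0.621). The reads cover the 3' end of transcripts, so a change elsewhere in TOP1 is not seen by them.

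**Figure D2:**
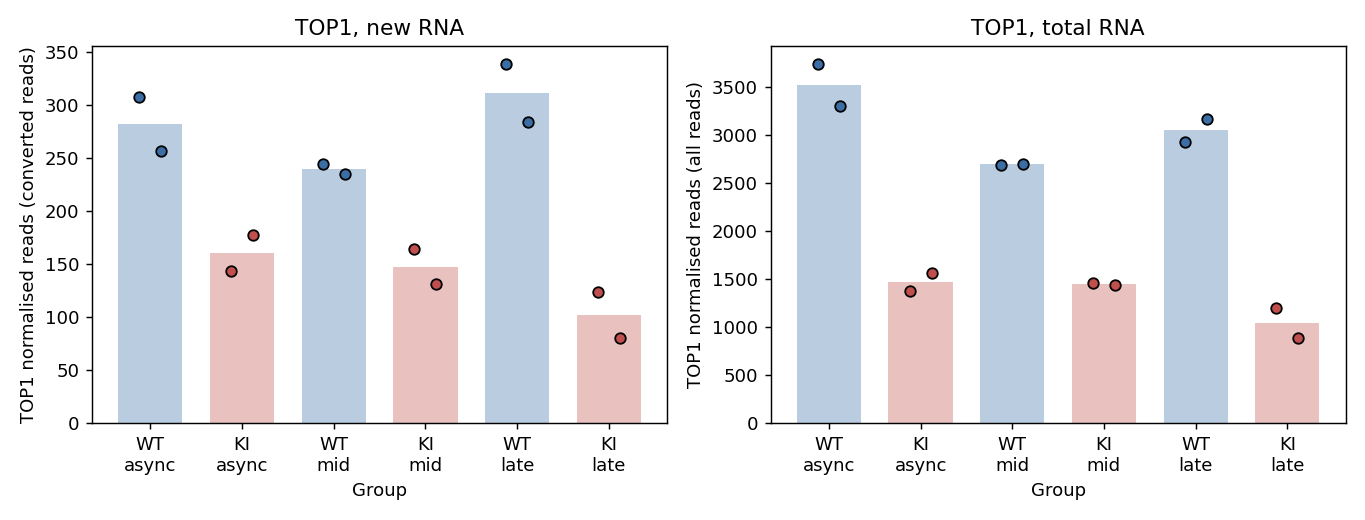
Normalised TOP1 reads (vertical axes) per library and group, for converted reads on the left and all reads on the right; points are libraries and bars are group means. Total TOP1 RNA was lower in KI than in WT at mid and at late, 1450 against 2692 and 1042 against 3048 on average.

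In mid mitosis, KI cells had less new RNA of FOS, an immediate early transcription factor, which was 8.54-fold lower (log2 -3.10, SE 0.58, n = 2 per group; limma-trend, adjusted p = 0.0124). It had 165 and 46 converted reads in the WT replicates and 7 and 10 in the KI replicates. FBXO5, an inhibitor of the anaphase-promoting complex, was 11-fold lower (log2 -3.46, SE 0.72; limma-trend, adjusted p = 0.0265), and the histone gene H4C3 was 4.55-fold lower (log2 -2.19, SE 0.33; limma-trend, adjusted p = 0.00146). FBXO5 had few reads, 37.8 ± 3.72 normalised converted reads in WT and 2.81 ± 2.07 in KI (SD, n = 2 each). MAGT1, a magnesium transporter, was 5.92-fold lower, ARRDC3, an arrestin-like adaptor, 3.52-fold lower, and SAAL1 5.11-fold lower. The replication helicase subunit MCM6 was 3.44-fold lower, topoisomerase 2 alpha, TOP2A, 3-fold lower, the chaperone HSPH1 2.47-fold lower and the alpha-tubulin genes TUBA1A, TUBA1B and TUBA1C 3.33-fold, 2.08-fold and 2.11-fold lower. The tubulin genes are near-identical copies, so reads shared among them are uncertain. TRIB1, a pseudokinase of the immediate early list, was 2.77-fold lower, DDX10, a helicase of ribosome biogenesis, 2.89-fold lower and EIF1AD 12.9-fold lower.

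Higher in KI at mid were the long noncoding RNA LNCAROD at 7.12-fold (log2 2.83, SE 0.46, n = 2 per group; limma-trend, adjusted p = 0.00322) and KIF23, a kinesin of the cytokinetic midzone, at 2.25-fold. TM4SF18 had no converted reads in WT at mid and was at least 9.15-fold higher in KI against a floor of 3 reads per library. PDCD7, a subunit of the minor spliceosome, was 4.03-fold higher. CDC16, a subunit of the anaphase-promoting complex, was 31.3-fold higher, TPRKB 3.92-fold and the ligand EFNA1 2.56-fold higher, while their total RNA did not pass the test. NGRN was 4.4-fold lower in new RNA, and its total RNA did not pass either. In all, 29 of 7927 genes passed for new RNA, 9 higher and 20 lower (limma-trend with Benjamini-Hochberg adjustment), and 28 of them had the same direction in total RNA, with 20 also called there. In total RNA 64 of 11563 genes passed, 24 higher and 40 lower. The authors' deposited table calls 56 genes in new and 148 in total RNA. With scaling by all reads the new RNA split became 7 higher and 42 lower, and the median of all genes moved to -0.24. Without KI mid replicate 1, KI mid replicate 2, WT mid replicate 1 or WT mid replicate 2, the new RNA count fell to 6, 8, 9 and 11, and the total RNA count to 15, 17, 20 and 14. The balance in new RNA turned to 5 higher and 4 lower without WT mid replicate 1 and to 8 higher and 3 lower without WT mid replicate 2. When only the groups compared entered the fit, total RNA gave 80 higher and 79 lower.

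Of 40 measured immediate early genes, 34 had a lower point value in KI at mid and 2, FOS and TRIB1, passed over all genes. Adjusted over the list alone, 10 were lower, among them FOSB (log2 -3.01, SE 0.84), KLF6 (-1.51, SE 0.46), DUSP1 (-1.49, SE 0.54) and ATF3 (-1.48, SE 0.50). These 4 did not pass over all genes and were chosen after their values were seen. The list was lower by camera (adjusted p = 6.17e-07), with adjusted p = 0.391 with an estimated correlation. G2/M genes had a higher camera result (adjusted p = 0.0187; adjusted p = 0.38 with an estimated correlation), with 1 member higher and 1 lower over all genes and 2 higher and 3 lower adjusted over the list alone; with scaling by all reads the called members were 0 higher and 2 lower. Ribosomal protein genes had a lower one (adjusted p = 0.0187; adjusted p = 0.497 with an estimated correlation), with no member called over all genes or adjusted over the list alone. Converted shares of its members RPL30 and RPS19 in both genotypes, RPS20 in WT and RPS15 in KI differed by 4-fold or more between the mid replicates. In total RNA, the cholesterol synthesis and G1/S lists were lower by camera (adjusted p = 1.37e-05 for each; adjusted p = 0.0733 and adjusted p = 0.0693 with an estimated correlation). Adjusted over the list alone, 2 G1/S members and no cholesterol synthesis member were lower. Topoisomerases had a median of 0.02, a mean of -0.23 and a lower camera result in total RNA (adjusted p = 0.0281; adjusted p = 0.155 with an estimated correlation), with 2 members lower over all genes and 3 adjusted over the list alone.

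In late mitosis, KI cells had more new RNA of the ribosomal protein genes RPL34 (2.44-fold; log2 1.29, SE 0.16, n = 2 per group; limma-trend, adjusted p = 0.000118), RPL4 (2.53-fold) and RPL26 (2.36-fold). The chaperones HSP90AA1 and HSPA8 were 2.16-fold and 3.29-fold higher, DUSP6, a phosphatase that acts on ERK, 2.24-fold higher, KIF23 2.21-fold higher, PDCD7 3.81-fold higher and MYL12B, a myosin light chain, 2.18-fold higher. Total RNA of these 9 genes was higher as well, from 1.68-fold for HSP90AA1 to 3.22-fold for HSPA8. CDC16 (13.8-fold), DPF2 (5.9-fold) and the tight junction gene CLDN7 (2.69-fold) were higher in new RNA, while their total RNA did not pass the test (limma-trend, adjusted p = 0.284, 0.479 and 0.0759). TM4SF18 had 1.33 ± 1.88 normalised converted reads in WT and 42.2 ± 18.9 in KI (SD, n = 2 each; limma-trend, adjusted p = 0.0493). SRP9, ABRACL and ABHD3 were also higher, by 6.21-fold, 4.27-fold and 3.77-fold.

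Lower in KI at late were MAL2, a protein of apical membrane transport (4.49-fold; log2 -2.17, SE 0.23, n = 2 per group; limma-trend, adjusted p = 1.57e-05), H4C3 (4.31-fold), TUBA1A (4.28-fold), HSPH1 (3.13-fold) and MCM6 (2.94-fold). The cell cycle kinase CDK2 was 2.24-fold lower, the mitotic kinase AURKB 1.76-fold, the spindle checkpoint gene BUB3 2.22-fold, the transcription factor MYBL2 4.84-fold, keratin 19, KRT19, 2.3-fold and integrin alpha 2, ITGA2, 2.42-fold lower. HDDC3 was 16.6-fold lower in new RNA, while its total RNA did not pass the test (limma-trend, adjusted p = 0.164), RAB2B was 8.24-fold, the transporter ABCC2 4.75-fold and PKIB, an inhibitor of protein kinase A, 4.55-fold lower. TOP2A was 4.33-fold lower in total RNA (log2 -2.12, SE 0.17; limma-trend, adjusted p = 2.08e-05) and TOPBP1 2.62-fold.

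At late, 80 of 7927 genes passed for new RNA, 40 higher and 40 lower, and 903 of 11563 for total RNA, 415 higher and 488 lower (limma-trend with Benjamini-Hochberg adjustment). The authors' deposited table calls 149 and 1022. Of the new RNA calls, 79 had the same direction in total RNA and 71 were called there. With scaling by all reads, 17 were higher and 58 lower in new RNA, and the median of all genes moved to -0.18. Without KI late replicate 2, KI late replicate 1 or WT late replicate 2 the new RNA count fell to 22, 37 and 52, and without KI late replicate 2 or WT late replicate 2 the total RNA count fell to 560 and 533. The even split of new RNA became 7 higher and 15 lower without KI late replicate 2, 10 and 27 without KI late replicate 1 and 43 and 19 without WT late replicate 1. Without the last of these the total RNA balance turned to 405 higher and 300 lower. When only the groups compared entered the fit, 137 genes passed in total RNA. G1/S genes were lower by camera (adjusted p = 0.013; adjusted p = 0.288 with an estimated correlation), with CDK2 and MCM6 as the 2 members lower over all genes and 2 lower adjusted over the list alone. Ribosomal protein genes were higher (adjusted p = 0.0115; adjusted p = 0.662 with an estimated correlation), with 3 members higher and 1 lower over all genes and 5 higher and 2 lower adjusted over the list alone. Converted shares of some members differed between the WT late replicates, with 9.29% and 45.3% for RPL7, 6.52% and 42.8% for RPL36A, 4.27% and 39.7% for RPS25 and 35% and 8.92% for RPL30, and none of these 4 was called. G2/M genes were higher (adjusted p = 0.0455; adjusted p = 0.295 with an estimated correlation), with 2 members higher and 2 lower over all genes and 5 higher and 5 lower adjusted over the list alone. The called members were 2 higher and 1 lower for ribosomal proteins and 1 higher and 2 lower for G2/M with scaling by all reads. Topoisomerases were lower (adjusted p = 0.0455; adjusted p = 0.305 with an estimated correlation), with TOP1 and TOP2A lower adjusted over the list alone. In total RNA G1/S genes were lower (adjusted p = 0.000984; adjusted p = 0.123 with an estimated correlation), with 10 of 63 members lower over all genes and 18 lower and 2 higher adjusted over the list alone. Cholesterol synthesis genes were lower (adjusted p = 0.00233; adjusted p = 0.132 with an estimated correlation), with 7 of 30 lower over all genes and 8 adjusted over the list alone.

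The KI against WT difference was compared between mid and late by an interaction term. TPRKB changed most: its new RNA went from 111 ± 24.4 to 344 ± 41.9 normalised reads in WT and from 437 ± 72.5 to 84.3 ± 9.22 in KI (SD, n = 2 each; log2 difference -3.99, SE 0.37; limma-trend, adjusted p = 1.43e-06). DPF2, a subunit of the BAF chromatin remodeller, fell in WT from 147 ± 47.0 to 24.5 ± 0.876 and was at 139 ± 14.7 and 155 ± 55.5 in KI (SD, n = 2 each; log2 difference 2.60; limma-trend, adjusted p = 0.0475). RPL34 went from 1428 ± 5.70 to 940 ± 117 in WT and from 1439 ± 44.8 to 2292 ± 151 in KI (SD, n = 2 each; log2 difference 1.28; limma-trend, adjusted p = 0.0475). These were the 3 genes that passed in new RNA, and limma-voom called 11. Their total RNA did not pass, and that of TPRKB and DPF2 had log2 differences of 0.1 and -0.05, opposite in sign to new RNA. In total RNA 0 genes passed by limma-trend, 1224 had an unadjusted p below 0.05, and limma-voom called 8. Without KI late replicate 1, WT late replicate 1 or WT late replicate 2, 85, 32 and 10 genes passed in total RNA. In new RNA the count was 7 without WT late replicate 1 or KI late replicate 1, and 1 without KI late replicate 2, KI mid replicate 1, WT mid replicate 1 or WT mid replicate 2. The immediate early list had a positive interaction by camera (adjusted p = 5.92e-06; adjusted p = 0.525 with an estimated correlation), with FOS, KLF6 and HES1 as the 3 members higher adjusted over the list alone. The converted share of KLF6 was 3.27% and 18.2% in the WT late replicates. The ribosomal protein list also had a positive interaction by camera (adjusted p = 5.49e-06; adjusted p = 0.583 with an estimated correlation), with RPL34 as the 1 member higher adjusted over the list alone.

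The share of CDC16 reads that were converted ran from 42.5% (95% Wilson interval 37.3% to 47.9%) to 51.4% (46.7% to 56.2%) in the 6 KI libraries. In the 6 WT libraries it ran from 1.44% (0.617% to 3.33%) to 13.4% (10.6% to 16.9%). For TPRKB the share was 10.2% (8.77% to 11.9%) and 10.3% (8.26% to 12.8%) in WT at mid and 36.4% (33.2% to 39.6%) and 33.9% (31.1% to 36.8%) at late. In asynchronous WT cells it was 39.2% in replicate 1 (95% Wilson interval 36.6% to 41.8%) and 7.05% in replicate 2 (5.76% to 8.61%). PIN4P1, a pseudogene whose reads can be shared with its parent gene, had 58.7% (54% to 63.3%) and 5.99% (3.72% to 9.51%) in the WT mid replicates.

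**Figure D3:**
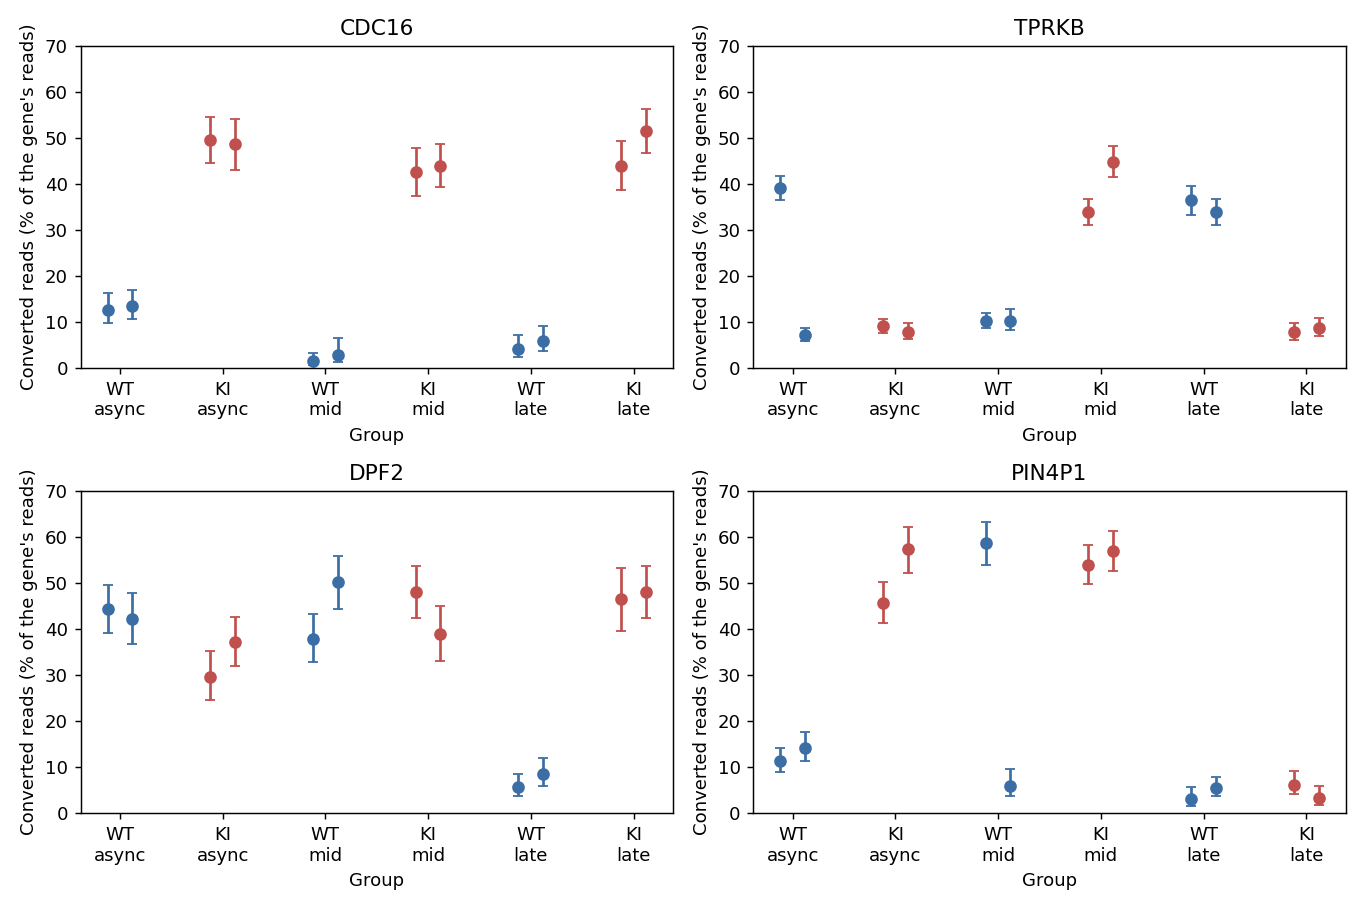
Converted reads as a share of all reads of CDC16, TPRKB, DPF2 and PIN4P1 (%, vertical axes) in each library by group; points are libraries and bars are 95% Wilson intervals, which cover counting error only. The TPRKB shares of the 2 asynchronous WT libraries, 39.2% and 7.05%, lie apart although both belong to 1 group.

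From mid to late mitosis in KI cells, new RNA of HES1, a transcriptional repressor downstream of Notch, rose 8.24-fold (log2 3.04, SE 0.53, n = 2 per group; limma-trend, adjusted p = 0.0139). ARRDC3 rose 4.77-fold and RSRP1 3.46-fold, while NLN, a peptidase, fell 3.35-fold, TPRKB 5.11-fold and PIN4P1 16.3-fold. ARRDC3 and RSRP1 also rose in total RNA, 6.8-fold and 2.44-fold, while total RNA of NLN, TPRKB and PIN4P1 did not pass the test. In WT cells, SLC39A9, a zinc transporter, rose 2.21-fold (SE 0.21 on the log2 scale, n = 2 per group; limma-trend, adjusted p = 0.0351), TPRKB rose 3.1-fold, and RCC2, a protein of the centromere and spindle, and DPF2 fell 3.05-fold and 5.64-fold. None of these 4 passed in total RNA by limma-trend, where the log2 values were 0.66 for SLC39A9 and -1.25 for RCC2 and, against the direction of new RNA, -0.1 for TPRKB and 0.14 for DPF2. In total RNA of WT cells H4C3 rose 2.53-fold, BTG1, an antiproliferative gene, 2.09-fold and GADD45B, a stress-inducible gene, 4.01-fold, and HSPA8 fell 2.82-fold. In new RNA 6 genes passed in KI, 3 in each direction, and 4 in WT, 2 in each direction. In total RNA 4 passed in KI, all higher, and 58 in WT, 35 higher and 23 lower (limma-trend with Benjamini-Hochberg adjustment). With scaling by all reads 7 genes were higher and 3 lower in new RNA of KI, with the median of all genes at 0.12. The authors' deposited table calls 18 and 39 genes in new RNA and 23 and 136 in total RNA.

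These counts moved with single libraries. For new RNA in WT they were 2 without WT mid replicate 1, 12 without WT mid replicate 2 and 17 without WT late replicate 1, where 1 was higher and 16 lower. In KI they were 2 without KI mid replicate 1 and 3 without KI late replicate 1, all 3 lower, and without KI mid replicate 2 the split was 6 higher and 1 lower. For total RNA in WT they were 3, 31, 14 and 308 without WT mid replicate 1, WT mid replicate 2, WT late replicate 2 and WT late replicate 1. Without WT late replicate 1 the balance turned to 73 higher and 235 lower. In KI they were 55 without KI late replicate 1, 2 without KI mid replicate 1 and 1 without KI mid replicate 2 or KI late replicate 2. The immediate early list was higher at late in KI by camera (adjusted p = 0.00146; adjusted p = 0.574 with an estimated correlation), with HES1, SGK1, KLF10 and BTG1 as the 4 members higher adjusted over the list alone. In WT it was lower (adjusted p = 0.0436; adjusted p = 0.651 with an estimated correlation), with 1 higher and 2 lower adjusted over the list alone. The WT late replicates differed for its member KLF6, with converted shares of 3.27% and 18.2%. In total RNA of WT the list had a median of 0.18, with 2 members higher and 0 lower over all genes and 9 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.139). Ribosomal protein genes were higher in KI (adjusted p = 0.00353; adjusted p = 0.574 with an estimated correlation), with 2 higher and 1 lower adjusted over the list alone. In WT they were lower (adjusted p = 0.00867; adjusted p = 0.651 with an estimated correlation), with 2 lower adjusted over the list alone. Converted shares of RPL30 differed between replicates in 3 of these 4 groups, with 49% and 8.3% in WT at mid, 35% and 8.92% in WT at late and 42.6% and 6.86% in KI at mid. The p53 target list was higher in KI (adjusted p = 0.0171; adjusted p = 0.574 with an estimated correlation), with 3 members higher adjusted over the list alone.

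In asynchronous cells, KI had more new RNA of ITGB8, integrin beta 8, at 7.55-fold (log2 2.92, SE 0.47, n = 2 per group; limma-trend, adjusted p = 0.0474). The transcription factor KLF2 was 2.51-fold and the stress cytokine GDF15 2.25-fold higher, and PIN4P1 3.45-fold higher in new RNA, while its total RNA did not pass and lay the other way (log2 -0.18). NRIP1, a nuclear receptor corepressor on chromosome 21, had no reads in KI and 77 ± 22.5 normalised converted reads in WT (SD, n = 2), so it was at least 37-fold lower in KI against a floor of 3 reads per library, and at least 102-fold lower in total RNA. NGRN and HDDC3, both on chromosome 15, were 3.26-fold and 4.7-fold lower in new RNA, and their total RNA did not pass the test. Of 8751 genes 8 passed in new RNA, 5 higher and 3 lower, and of 11409 genes 3 passed in total RNA, 2 higher and 1 lower (limma-trend with Benjamini-Hochberg adjustment). The authors' deposited table calls 40 and 174. Without WT async replicate 2, 441 genes passed in new RNA and 1830 in total RNA. Without WT async replicate 1 there were 74 and 73, and without KI async replicate 1 and KI async replicate 2 the total RNA count was 7 and 17. The balance of new RNA then turned to 4 higher and 7 lower without KI async replicate 1 and to 5 and 7 without KI async replicate 2, and that of total RNA to 2 higher and 5 lower without KI async replicate 1.

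Of 43 measured immediate early genes in asynchronous cells, 39 had a higher point value in KI. KLF2 passed over all genes, and 15 were higher and 1 lower adjusted over the list alone, among them EGR2 (log2 2.61, SE 0.55), CCN2 (1.65, SE 0.31), KLF6 (0.91, SE 0.16) and EGR1 (0.79, SE 0.15). EGR2, CCN2 and EGR1, like CDKN1A and MDM2 here, were chosen after their values were seen, and none of the 5 passed over all genes. The list was higher by camera (adjusted p = 1.68e-16; adjusted p = 0.14 with an estimated correlation). The p53 targets GDF15, CDKN1A (log2 1.24, SE 0.25), GADD45A (1.22, SE 0.22) and MDM2 (0.84, SE 0.19) were among 8 members higher adjusted over the list alone, and the list was higher by camera (adjusted p = 6.76e-08; adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis genes were lower (adjusted p = 2.03e-06; adjusted p = 0.14 with an estimated correlation), with RRS1 and DDX10 as the 2 members lower adjusted over the list alone. Ribosomal protein and MYC target genes were lower by camera (adjusted p = 4.38e-05 and adjusted p = 0.000746; adjusted p = 0.392 for each with an estimated correlation). Cholesterol synthesis genes were higher (adjusted p = 0.0079; adjusted p = 0.387 with an estimated correlation), with 1 member higher adjusted over the list alone. No ribosomal protein or MYC target member passed adjusted over the list alone.

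Against asynchronous cells, mitotic cells had less new RNA of EGR1, an immediate early transcription factor, by 3.73-fold in WT at mid (log2 -1.90, SE 0.19) and 5.6-fold in KI at mid (log2 -2.49, SE 0.19; limma-trend, adjusted p = 3.23e-06 and 2.09e-08; n = 2 per group). ID1, an inhibitor of differentiation, was 7.46-fold and 11.9-fold lower, TUBA1B 2.7-fold and 4.87-fold, H4C3 3.06-fold and 14.4-fold and TOP2A 2.44-fold and 6.39-fold lower at mid in WT and KI. The cyclin genes CCNA2 and CCNB1 were 1.95-fold and 2.05-fold higher at mid in WT and 2.88-fold and 3.07-fold higher in KI, and NOP16, a ribosome biogenesis gene, 2.76-fold and 3.39-fold higher. Total RNA of CCNA2, CCNB1 and NOP16 was higher and that of ID1, TUBA1B, H4C3 and TOP2A lower in the same comparisons. TOP1 did not pass in new RNA, with log2 -0.23 in WT at mid (limma-trend, adjusted p = 0.678) and -0.13 in KI at mid (limma-trend, adjusted p = 0.805), while its total RNA was 1.42-fold lower in KI at late than in asynchronous KI cells (limma-trend, adjusted p = 0.0436). Whether these changes differ between WT and KI was tested by an interaction term, reported with the additional observations. RPL30 was 7.6-fold higher in WT at mid with 4366 ± 4693 normalised reads (SD, n = 2), and its converted share was 49% in replicate 1 (95% Wilson interval 48.2% to 49.7%) and 8.3% in replicate 2 (7.76% to 8.86%).

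For new RNA 395 of 9205 genes passed in WT at mid, 226 higher and 169 lower, and 619 at late, 401 higher and 218 lower (limma-trend with Benjamini-Hochberg adjustment). In KI 1144 passed at mid, 552 higher and 592 lower, and 1002 at late, 544 higher and 458 lower. For total RNA 1071 (602 higher) and 1686 (1052 higher) passed in WT at mid and late, and 1902 (1046 higher) and 1891 (1042 higher) in KI. These directions are relative to the converted reads of each library. With scaling by all reads the splits were 57 higher and 703 lower in WT at mid, 105 and 647 in WT at late, 88 and 2080 in KI at mid and 113 and 1671 in KI at late. The medians of all genes were then -0.55, -0.52, -0.85 and -0.75, against -0.11, -0.11, -0.17 and -0.16 with the deposited scaling, and the called G2/M members at mid were 1 higher and 4 lower in WT and 6 higher and 7 lower in KI. 

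Without WT mid replicate 1, WT mid replicate 2, WT async replicate 1 or WT async replicate 2 the new RNA count for WT at mid was 187, 181, 155 and 171. Without either WT mid library the balance turned, to 87 higher and 100 lower without replicate 1 and to 68 and 113 without replicate 2. For WT at late it was 189 without WT late replicate 1 and 249 without WT async replicate 2. For KI at mid it was 582, 737, 356 and 464 without KI mid replicate 1, KI mid replicate 2, KI async replicate 1 and KI async replicate 2, and without the last 2 the balance turned to 201 higher and 155 lower and to 282 and 182. For KI at late it was 657, 310 and 395 without KI late replicate 1, KI async replicate 1 and KI async replicate 2. Its balance turned to 311 higher and 346 lower without KI late replicate 1 and to 344 and 421 without KI late replicate 2. In total RNA, WT at mid gave 395, 434 and 609 without WT mid replicate 1, WT mid replicate 2 and WT async replicate 1, and WT at late 980 and 901 without WT late replicate 1 and WT late replicate 2. KI at mid gave 763, 846, 631 and 817 without KI mid replicate 1, KI mid replicate 2, KI async replicate 1 and KI async replicate 2, with 415 higher and 431 lower without KI mid replicate 2. KI at late gave 1235, 679 and 734 without KI late replicate 2, KI async replicate 1 and KI async replicate 2.

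With the deposited scaling, 30 of 43 immediate early genes were lower in KI at mid and 34 adjusted over the list alone (camera adjusted p = 2.27e-22; adjusted p = 0.0122 with an estimated correlation). In WT at mid 9 were lower and 1 higher, and 16 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.000163; adjusted p = 0.231 with an estimated correlation). In total RNA of WT 10 of 44 immediate early genes were higher and 4 lower at mid, 15 and 9 adjusted over the list alone (camera adjusted p = 0.0966). At late 14 were higher and 6 lower, 17 and 6 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.136 with an estimated correlation). In total RNA of KI 4 were higher and 13 lower at mid, 6 and 15 adjusted over the list alone, and the list was lower by camera (adjusted p = 0.000864; adjusted p = 0.0923 with an estimated correlation). At late in KI 5 were higher and 10 lower, 9 and 11 adjusted over the list alone (camera adjusted p = 0.542). G2/M genes were higher in WT at mid, with 14 members higher and 2 lower, 17 and 4 adjusted over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.0145 with an estimated correlation). In KI at mid 20 were higher and 4 lower, 27 and 5 adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.00529 with an estimated correlation). G1/S genes were lower at mid in WT (camera adjusted p = 0.00199; adjusted p = 0.0369 with an estimated correlation) and in KI (camera adjusted p = 0.000182; adjusted p = 0.0122 with an estimated correlation), with 3 lower in WT and 17 lower and 2 higher in KI adjusted over the list alone. In KI at late the ribosomal protein list had a median of 0.31, a mean of -0.09 and a higher camera result (adjusted p = 0.00439; adjusted p = 0.492 with an estimated correlation), with 12 higher and 5 lower over all genes and 16 higher and 7 lower adjusted over the list alone. The called members were 3 higher and 14 lower with scaling by all reads.

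The KI against WT comparisons at mid and late share no library, but they come from the same fit, with the same variance estimate for each gene. Fisher's exact test takes the lists as independent and can therefore overstate their overlap. A fixed difference of the KI clone, which is not separable from genotype, would also recur in both states. In new RNA the calls at mid and late overlapped by 5 higher genes, CDC16, TM4SF18, PCLAF, PDCD7 and KIF23, where independent lists give 0.0454 (Fisher's exact test, p = 3.14e-10). They overlapped by 6 lower genes, MCM6, H4C3, MAL2, TUBA1A, HSPH1 and NGRN, where independent lists give 0.101 (Fisher's exact test, p = 4.11e-10). In total RNA 19 of the 24 genes higher at mid and 33 of the 40 lower at mid were also called at late (Fisher's exact test, p = 8.43e-24 and 2.13e-39). Among lower genes of new RNA, NGRN was shared by asynchronous cells with mid and late, and HDDC3 with late. In total RNA ITGB8, TM4SF18 and NRIP1 were shared by each pair of states. The correlation across genes of the log2 fold changes at mid and late was 0.17 in new and 0.31 in total RNA; genes are not independent replicates.

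Because topoisomerase 1 relieves supercoils along transcribed genes, fold changes were set against gene length. Spearman's rho across genes was 0.048, 0.017 and 0.101 in new RNA at mid, late and in asynchronous cells, and 0.077, 0.08 and 0.149 in total RNA. The difference between replicates of 1 group had a rho with length of 0.002 to 0.114 in size in new RNA and 0.019 to 0.176 in total RNA over the 6 groups. At mid both replicate values were below that of the comparison, 0.014 and 0.035 in new RNA and 0.049 and 0.06 in total RNA. At late and in asynchronous cells 1 of the 2 replicate values was above it, 0.086 and 0.114 in new RNA and 0.146 and 0.176 in total RNA. Genes are not independent replicates, and length was known for 98.3% of genes tested in new RNA and at least 97.7% in total RNA.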

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

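Of the tests weighed here, those on converted shares were chosen after the result was seen, as were the comparisons of genotype effects between mitotic and asynchronous cells. The tests on the late libraries and on mitotic exit were written down before their own outcomes were seen. The test on mitotic exit uses mid against asynchronous WT cells, a comparison added after the files were seen.

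In new RNA the KI against WT difference changed between mid and late for TPRKB (log2 -3.99), RPL34 (1.28) and DPF2 (2.6), by an interaction term in limma-trend. Between mid mitotic and asynchronous cells it changed for CDC16 (log2 3.34), FBXO5 (-4.36), ASNS (1.92), the overlapping readthrough gene CZ1P-ASNS (1.91), SLC38A2 (-1.97), GADD45A (-2.43), H4C3 (-2.23), CDKN1A (-2.02) and FOS (-3.78). FOS new RNA was 103 ± 60.2 in WT and 10.4 ± 4.19 normalised reads in KI at mid, against 34.5 ± 10.8 and 56.3 ± 19.6 in asynchronous cells (SD, n = 2 each). GADD45A was 98.3 and 41.7 at mid and 161 and 377 in asynchronous cells. At mid 3 genes were positive and 6 negative, with scaling by all reads 1 and 10, with the median of all genes at -0.27, and with a pseudocount of 0.5 the balance turned to 3 and 1. This set of 9 genes at mid fell to 0 without WT async replicate 1, KI async replicate 1 or KI async replicate 2, to 1 without WT mid replicate 1, WT mid replicate 2 or KI mid replicate 2, and to 5 without KI mid replicate 1 or WT async replicate 2, with 4 positive and 1 negative in the last. By limma-trend 334 to 406 genes had an unadjusted p below 0.05 in the fits that gave 0. Between late mitotic and asynchronous cells the difference changed for DPF2 (log2 2.97), the 1 gene that passed, while limma-voom called 12. By limma-trend 0 genes passed with scaling by all reads, where 462 had an unadjusted p below 0.05 and the median of all genes was -0.23. It was 0 as well without WT late replicate 2, WT async replicate 1 or KI async replicate 1 (442, 460 and 313 at unadjusted p below 0.05), and 3 without KI late replicate 1, KI late replicate 2 or WT async replicate 2.

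In total RNA the KI against WT difference changed between late mitotic and asynchronous cells for H4C3 (log2 -2.73), TOP2A (-1.95), SAPCD2 (1.48), SLC38A2 (-1.42), TUBA1A (-1.8), LOC727896 (1.63), MARS1 (1.39), NOL7 (1.47), BUB3 (-1.29) and GDF15 (-1.41). H4C3 had 5397 ± 542 normalised reads in WT and 809 ± 36.4 in KI at late, against 8193 ± 2065 and 8185 ± 2217 in asynchronous cells (SD, n = 2 each). TOP2A had 1253 ± 121 and 289 ± 33.2 at late, against 2373 ± 308 and 2108 ± 116 (SD, n = 2 each). Without WT async replicate 2, WT async replicate 1 or WT late replicate 2 the count was 26, 23 and 18, without WT late replicate 1 or KI late replicate 2 it was 6, and without either asynchronous KI library it was 4. Between mid mitotic and asynchronous cells 0 genes passed in total RNA by limma-trend, 671 had an unadjusted p below 0.05, and limma-voom called 2. Without WT mid replicate 1 the count was 1, and without WT async replicate 2 it was 8.

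In the comparisons of KI with WT, of late with mid and of genotype by time, new RNA calls with little change of total RNA covered 9 genes: TPRKB, DPF2, NLN, PIN4P1, EFNA1, NGRN, CDC16, CLDN7 and HDDC3. Converted reads not from labelling could come through sequence variants or masking that differed between libraries. They were looked for as jumps of the converted share between replicates. Up to 31 genes per 1000, in WT at mid, jumped 4-fold or more, beyond counting error by adjusted Fisher's exact tests. Of 905 such jumps over all groups, 77.3% had under 200 reads in the shallower library. Spread between libraries beyond counting error was not modelled, so the count cannot separate it from variants or masking. In WT at late nearly all jumps went 1 way, with the share higher in replicate 2. The median share over genes was 7.87% in WT late replicate 1 and 10.9% in WT late replicate 2. These 2 libraries thus differed in converted share across genes, and every comparison with WT at late uses both. Deeper genes jumped as well. In the WT mid replicates RPL30 had 49% of 17840 reads and 8.3% of 9680, and MRPS7 28.1% of 2206 and 5.63% of 1421. Among the 9 genes 22.2% jumped within a group (TPRKB and PIN4P1), against 5.99% of 6193 others with as many reads (Fisher's exact test, p = 0.0981). Their highest share lay above the 99th percentile of all genes in 77.8% of them, but FOS, a short-lived RNA, also reached 96.5% in asynchronous KI replicate 2 (95% Wilson interval 88.1% to 99%), so a change of synthesis is not excluded. Both explanations stay open, since no unlabelled library was used here, and a variant of the KI clone may account for genes such as CDC16 whose shares follow the genotype.

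More total RNA calls between KI and WT were made at late (903) than at mid (64), while 0 genes passed the interaction in limma-trend (1224 at unadjusted p below 0.05, 8 by limma-voom). When only the groups compared entered the fit, 137 genes passed at late and 159 at mid, so the larger count at late holds for the fit of all mitotic libraries and not for this one. Within the fit of all mitotic libraries a single late library is argued against, since leaving out each of the 4 left at least 533 calls, against 64 at mid. KI cells being later or earlier in mitotic exit was tested by the correlation across 11554 genes with mid against asynchronous WT cells, which gave r = 0.111, between the bounds of 0.3 and 0.1 set for and against it. A difference in exit therefore stays open, as does the genotype itself, which is confounded with the clone.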

How the results depend on the processing

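The comparisons of mitotic with asynchronous cells, trimmed mean of M-values scaling, other pseudocounts, limma-voom, the requirement of a total RNA change, voom overlaps, the crossed pairing and the alternatives for the share of converted reads were tests chosen after the data were seen. No named gene changed sign under the alternatives run where its main value had passed the test. Genes named for their fold change were chosen for no overlap between the groups. Leaving out a library or changing the pseudocount could therefore not turn their sign, and is no test of it. Scaling by all reads turned the balance of higher and lower calls in new RNA between mitotic and asynchronous WT cells and between late and asynchronous KI cells, and the median of new RNA for genotype by time from -0.03 to 0.06. Trimmed mean of M-values scaling and limma-voom turned the balance between mid and asynchronous KI cells, to 654 higher and 537 lower and to 669 and 545. Leaving out single libraries turned further balances, most of them given with their comparison. Of 6661 values of named genes under alternatives, 5729 kept their side of the threshold, 926 lost the call and 6 gained it. The counts of calls below moved by over 1.5 times; where the alternative does not itself use fewer genes or samples, the cause was not tested. DESeq2 and its size factors in a count model, planned as alternatives, were not run. Leaving out mitochondrially encoded genes has no value, since none was measured.

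With no low-count filter, new RNA gave 2 calls for late against mid in WT and 2 in KI, 19 and 34 for KI against WT at mid and late, 1 for genotype by time and 15 in asynchronous cells; total RNA gave 9, 1, 32 and 511 for the first 4. With only the groups compared, new RNA in WT late against mid gave 2, and total RNA gave 7 there, 159 for KI against WT at mid and 137 at late. Scaled by all reads, new RNA gave 2 and 10 for late against mid in WT and KI, 49 for KI against WT at mid, 23 in asynchronous cells, 760 for mid against asynchronous WT, 2168 and 1784 for mid and late against asynchronous KI and 0 for genotype by state at late (462 at unadjusted p below 0.05). Trimmed mean of M-values scaling gave 23 in asynchronous cells. A pseudocount of 0.5 gave 1 for genotype by time and 1 in asynchronous cells, both lower, and 4 (3 higher and 1 lower) and 0 for genotype by state at mid and late in new RNA; a pseudocount of 5 gave 20 in asynchronous cells and 6 for genotype by state at late. Limma-voom on the recovered reads gave 57 in WT late against mid, 11 for genotype by time, 24 in asynchronous cells and 12 for genotype by state at late in new RNA. In total RNA it gave 118 in WT late against mid, 8 for genotype by time, 0 in asynchronous cells (1023 at unadjusted p below 0.05; limma-trend called 3), and 2 and 27 for genotype by state at mid and late. Only calls with a total RNA change of at least 0.5 numbered 2 and 3 for late against mid in WT and KI, 1 for genotype by time, 5 in asynchronous cells, 749 and 662 for mid and late against asynchronous KI and 0 for genotype by state at late.

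With an estimated correlation, 0 of the 48 list calls among 209 tests by camera held, and 26 of 51 among the 140 tests against asynchronous cells. For G1/S genes in new RNA of KI against WT at late, the estimated correlation was -0.01, below the preset 0.01. Their camera adjusted p still went from 0.013 to 0.288, so correlation alone does not account for that loss. With limma-voom calls the overlaps of new RNA were 3 higher and 2 lower for mid with asynchronous cells and 3 higher for late with asynchronous cells. In total RNA the overlaps of mid and late with asynchronous cells were then 0 in both directions, since limma-voom called 0 there. The share of converted reads, mitotic minus async, differed by -5.16 points by the median over genes, and -4.28 to -3.83 when 1 library was left out.

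The replicate numbers paired the libraries weakly at most. Over 6 pairs of mitotic groups, deviations of libraries with the same number correlated at 0 to 0.05 in new and 0 to 0.11 in total RNA. In asynchronous cells they correlated at -0.06 and -0.17. A small effect shared by replicate number in mitotic cells is not excluded. With the replicate block, new RNA gave 9 calls for late against mid in WT, 53 for KI against WT at mid and 21 in asynchronous cells. Total RNA gave 337 and 14 for late against mid in WT and KI, the first with its balance turned to 142 higher and 195 lower, and 114 and 1377 for KI against WT at mid and late. It gave 42 for genotype by time, 29 higher and 13 lower, where 0 passed by limma-trend without the block, and 5 for genotype by state at late. With the numbers crossed as a block, 89 genes in new and 243 in total RNA passed in asynchronous cells.

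Leaving out 1 library assumes that the lone library varies like the other groups. In new RNA the counts were then 2 to 17 and 2 to 7 for late against mid in WT and KI, 6 to 11 and 22 to 62 for KI against WT at mid and late, 1 to 7 for genotype by time and 11 to 441 in asynchronous cells. Against asynchronous cells they were 155 to 187 and 189 to 551 in WT and 356 to 737 and 310 to 765 in KI at mid and late, and 0 to 5 and 0 to 3 for genotype by state. In total RNA they were 3 to 308 and 1 to 55 for late against mid in WT and KI, 14 to 20 and 533 to 705 for KI against WT at mid and late, 0 to 85 for genotype by time and 7 to 1830 in asynchronous cells. Against asynchronous cells they were 395 to 1447 and 901 to 1739 in WT and 631 to 846 and 679 to 1306 in KI, and 0 to 8 and 4 to 26 for genotype by state. In new RNA 17.7% of simulated 2-fold changes at late were recovered; depth, the number of libraries and their spread were not separated.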

Other observations

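The comparisons with asynchronous cells given here were all chosen after the files were seen.

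Late against asynchronous cells, ribosome biogenesis genes were higher in new RNA of KI, with 11 of 52 members higher and 0 lower by limma-trend, both over all genes and adjusted over the list alone (camera adjusted p = 0.000174; adjusted p = 0.0134 with an estimated correlation). NOP16 was 3.9-fold higher, RRS1 2.62-fold and WDR43 2.07-fold (limma-trend, adjusted p = 1.42e-06, 0.00232 and 0.00251). With scaling by all reads 1 member was higher and 3 lower. In total RNA 21 of 57 were higher and 1 lower (camera adjusted p = 4.67e-09; adjusted p = 0.00597 with an estimated correlation), with 23 and 1 adjusted over the list alone. Topoisomerases were lower in total RNA, 6 of 13 (camera adjusted p = 0.000164; adjusted p = 0.0212 with an estimated correlation), with 6 lower and 1 higher adjusted over the list alone.

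In new RNA of mitotic WT cells the cystine transporter SLC7A11 was 7.86-fold lower at mid and 6.51-fold at late, and PSAT1, of serine synthesis, 3.11-fold and 4.73-fold lower (limma-trend, adjusted p = 2.77e-05, 4.22e-05, 0.000255 and 5.78e-06). GALNT5, a glycosyltransferase, was 7.5-fold higher at mid and 11.5-fold higher at late in WT, and 9.61-fold higher in total RNA at late.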
